A study of Mus musculus with 6 samples.

How the data were processed

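RNA sequencing was made from macrophages sorted as CD45+CD11b+F4/80+ cells from the colons of 10-week-old C57BL/6 mice with colitis induced by dextran sulfate sodium (DSS), a polymer that damages the colon lining when taken up in drinking water. CD45 marks blood-derived cells, and CD11b and F4/80 are surface proteins of the macrophage lineage. There were 3 wild-type (WT) samples and 3 samples from mice without Gsdmd (Gsdmd-/-), and groups and replicate numbers were taken from the sample labels. Libraries were run on the BGISEQ-500 sequencer, per the labels' protocols. Bowtie2 version 2.2.5 and the genome build GRCm38.p6 are named in the submitters' processing notes, and the program that turned alignments into gene values, its annotation, its use of strand and any filter on genes are not given in the sources used here. The labels do not say that the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 3 samples against 3 cannot go below a two-sided p of 0.1, so the model across all genes was used.

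The deposited tables hold 1 normalized value for each of 17067 genes per sample, all typed as mRNA, and no column states its unit. The deposited values were read as FPKM, fragment counts scaled by transcript length and by the mapped fragments of the library, because their sums differ between samples and their low values move in steps that scale with transcript length. Sums ran from 476271 to 485411 in WT and from 551502 to 565388 in Gsdmd-/- samples. No mitochondrially encoded gene is listed. Of the gene identifiers, 16950 were found in the RefSeq gene table of the same build, 16611 of them with the symbol the tables give. In 25 cases the symbol had been turned into a date, and it was replaced through the identifier. Coordinates are 1-based positions in GRCm38.p6 from that RefSeq table.

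Depth was estimated from the size of those steps in genes with 1 annotated transcript, which gave 20.3 M to 20.8 M fragments in WT and 20.6 M to 20.9 M in Gsdmd-/- samples. In simulated data with 11149 such genes, the largest error of this estimate was 0.462%. A chi-square test on the reads this depth implies, over genes with 20 to 2000 reads, gave 1.57 to 2.31 per degree of freedom for the 6 pairs within a group, with a largest p of 7.11e-154, and 29.7 to 41.0 for the 9 pairs between groups. Repeat libraries of 1 sample could also differ by more than counting noise, so this does not show that the samples are separate mice, and they were counted separately as the labels number them.

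Because the deposited values are not counts, genes were tested with limma version 3.58.1 in R version 4.3.3, with its trend and robust settings, on log2(FPKM + 1). Genes entered with at least 1 FPKM in at least 3 of the 6 samples. Log2 changes are Gsdmd-/- minus WT on that scale, which understates the change of genes at low level. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 are said to have risen or fallen. Before the data were examined, 33 gene lists were fixed: 19 of macrophage functions, 12 of markers of other cell types and 2 of cell stress. The 25 lists with at least 5 tested members were tested with camera from limma, two-sided, at a preset correlation of 0.01, and their p-values were adjusted together. Calls on the deposited values and with the trend on length and GC removed are given with the p at the preset and at an estimated correlation.

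The rule for the genes named was fixed at the same time. They are Gsdmd, the 12 genes that rose most and the 12 that fell most, up to 4 members of each list with the smallest p, and 11 genes of inflammasome, DNA sensing and interferon pathways whatever their p (Casp1, Casp4, Nlrp3, Aim2, Il1b, Il18, Cgas, Tmem173, Ifnb1, Isg15 and Cxcl10). The genes with the largest changes had to be past the threshold, to change at least 2-fold, to have groups that did not overlap and a mean level above the median, and symbols ending in Rik or of numbered predicted genes were left out. A gene outside this rule is said to be so where it is named.

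In simulated data for this comparison with 9913 tested genes, 200 of them changed, the test recovered 91% of genes changed by 0.5 and 100% of those changed by 1 on the log2 scale, and called 0.0721% of unchanged genes. A simulated trend on transcript length and GC between the groups, over 9929 tested genes, led the test to call 71.6% of unchanged genes. Removing the trend, over 9782 genes, brought that to 1.38%. Camera called the simulated list that had been moved and 0 of 20 random lists. These lists were simulated without the trend and with genes drawn independently. They do not show how often camera calls unmoved lists where members share a trend or are correlated.

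Transcript length and GC content came from GENCODE M21 protein-coding transcripts and were found for 9852 of the 10005 tested genes (98.5%). The removal of their trend, as splines with 5 degrees of freedom each in every sample, was added after seeing the data. The other alternatives were fixed beforehand: the replicate number as a block, each sample left out, no filter and a stricter filter of 5 FPKM, quantile normalization, rescaling to TPM, median ratio scaling, pseudocounts of 0.1 and 0.01, sample weights, limma without its trend and robust settings, an adjusted p under 0.1, an estimated correlation, fry (a rotation test) and camera on ranks. Count tests were not run, since the tables hold no counts. Tables were prepared with Python version 3.11.15, pandas version 2.3.3, NumPy version 2.4.6 and SciPy version 1.17.1, and plots with matplotlib version 3.10.9.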

Results

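Transcript levels were measured in colon macrophages of mice with DSS colitis, 3 samples from WT and 3 from Gsdmd-/- mice, to compare the macrophage transcriptome with and without Gsdmd. Gsdmd encodes gasdermin D, the protein that inflammatory caspases cleave into a pore that opens the cell membrane in pyroptosis. The libraries held an estimated 20.3 M to 20.9 M fragments each, so depth was nearly equal between groups. Across 10005 tested genes, Pearson correlations (across genes, which are not independent replicates) ran from 0.997 to 0.998 within groups and from 0.967 to 0.975 between groups. The first principal component held 90.5% of the variance and separated WT from Gsdmd-/- samples.

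Gsdmd (gene 69146, chromosome 15, positions 75862144 to 75867408 in GRCm38.p6) was lower in each Gsdmd-/- sample than in any WT sample. Its level was 98.1 ± 1.08 FPKM in WT and 29.1 ± 0.612 FPKM in Gsdmd-/- macrophages (SD, n = 3 each). It fell by 1.72 on the log2 scale (SE 0.0326, adjusted p = 1.12e-11), to 0.296 of the WT level. The samples were 97.7, 99.4 and 97.4 FPKM in WT and 28.5, 29.0 and 29.7 FPKM in Gsdmd-/-. The tables give 1 value per gene, so the part of the transcript behind the remaining level was not analysed here.

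Pla2g7, which encodes a secreted phospholipase that inactivates platelet-activating factor, rose from 10.0 ± 0.0954 to 61.9 ± 1.39 FPKM (SD, n = 3 each, log2 change 2.51, SE 0.0383, adjusted p = 2.74e-12). Timp1, an inhibitor of matrix metalloproteinases, rose from 19.4 ± 1.28 to 70.6 ± 1.68 FPKM (log2 change 1.81, adjusted p = 2.35e-10), and Ifnb1, which encodes interferon beta, from 84.9 ± 3.56 to 193 ± 4.47 FPKM (log2 change 1.17, adjusted p = 4.05e-10). Bgn, a matrix proteoglycan, and Mt2, a metallothionein, rose by 1.48 and 1.21 on the log2 scale. Among genes that fell, Gdf3, a growth factor of the TGF-beta family, went from 58.3 ± 2.36 to 17.0 ± 0.999 FPKM (log2 change -1.72, adjusted p = 3.76e-10), and Ptgs2, which encodes the prostaglandin-forming enzyme cyclooxygenase, from 49.0 ± 1.70 to 17.5 ± 1.10 FPKM (log2 change -1.44, adjusted p = 7.21e-10). The integrin genes Itga4 and Itgav fell by 1.56 and 1.53, the transcription factor gene Zeb2 by 1.45, the translational regulator Cpeb4 by 1.80, the aminopeptidase Lnpep by 1.61 and Dennd1b by 1.41 on the log2 scale. In GRCm38.p6, Pla2g7 lies on chromosome 17 at 43567994 to 43612202, Ifnb1 on chromosome 4 at 88522025 to 88522794 and Gdf3 on chromosome 6 at 122605403 to 122610087.

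Several genes with large changes share sequence or position with another gene, and their values are uncertain. Cerkl rose by 3.20 on the log2 scale, from 3.01 to 35.8 FPKM, and overlaps Itga4 over 624 bp. Cnbd2 (log2 change 1.78) overlaps Scand1 over 759 bp, and Eaf2 (1.99) overlaps Iqcb1. Dynlt1b (2.27) and the genes 9930111J21Rik1 (-2.36) and 9930111J21Rik2 (-1.72) have near-identical copies, H2-T10 (1.62) belongs to the MHC class I family, and Gapdh-ps15 (1.31) and Rpl31-ps12 (1.16) are pseudogenes. Of the genes above, Timp1 lies within Syn1, Itga4 overlaps Cerkl, and Pla2g7, Zeb2, Itgav, Dennd1b and Cpeb4 overlap annotated noncoding genes or pseudogenes, and the use of strand in counting is not known.

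**Figure D1:**
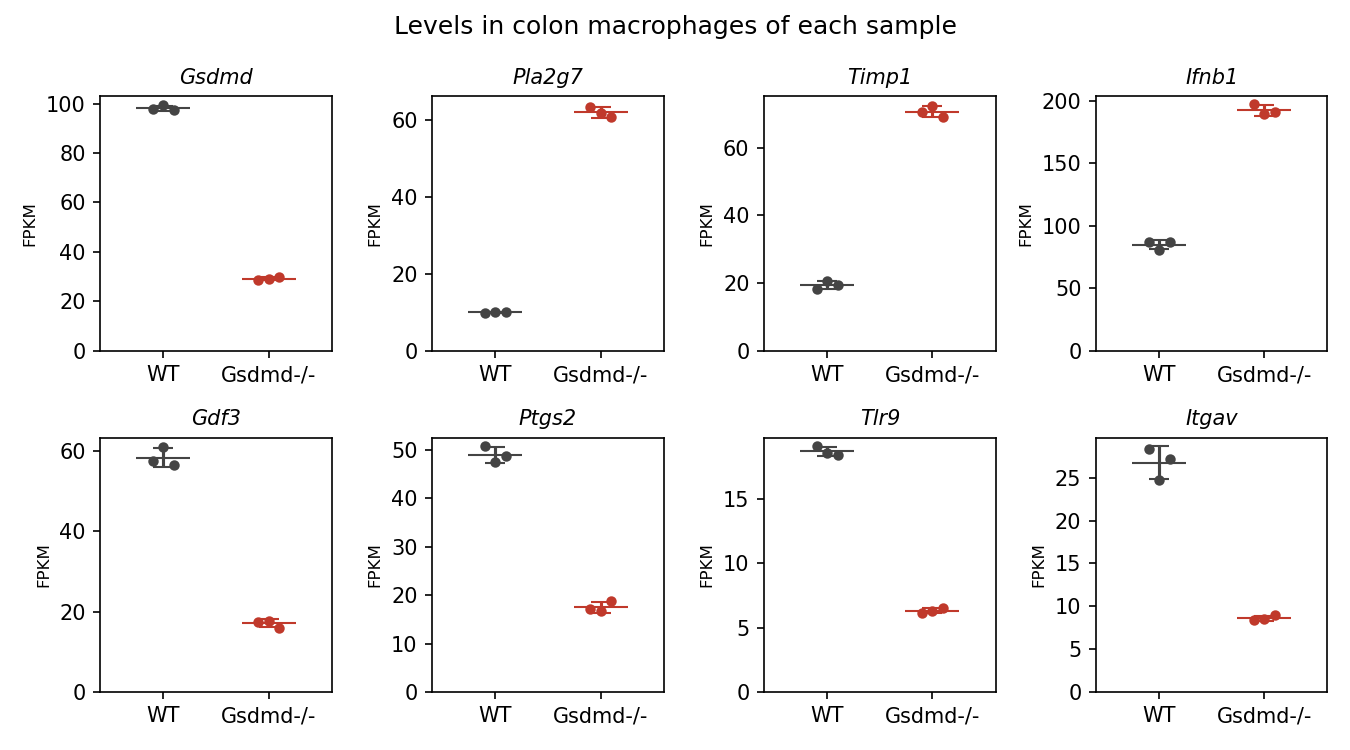
FPKM (vertical axes, from 0) of 8 genes in WT and Gsdmd-/- macrophages. Points are samples, long dashes are group means and bars are SD (n = 3 each); Gsdmd, Gdf3, Ptgs2, Tlr9 and Itgav were lower and Pla2g7, Timp1 and Ifnb1 higher in all 3 Gsdmd-/- samples, as for Ifnb1, with means of 84.9 FPKM in WT and 193 FPKM in Gsdmd-/-.

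Of the 10005 tested genes, 4059 rose and 3693 fell in Gsdmd-/- macrophages (limma, adjusted p under 0.05), 77.5% of those tested, and 75 rose and 220 fell at least 2-fold. The groups did not overlap for 7946 genes (79.4%), where chance gives 10% with 3 samples against 3. Most changes were small: the median absolute log2 change was 0.329, beside a median SD within groups of 0.0652. Rescaled to TPM, which took the median log2 change of all genes from 0.03 to -0.17, 2575 genes rose and 5352 fell, 32.5% of calls higher against 52.4%. The counts of genes that rose and fell at least 2-fold were 63 and 675 in TPM, 175 and 413 with a pseudocount of 0.1, and 192 and 452 with one of 0.01.

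Log2 changes followed transcript length and GC content across genes, with a Spearman rho of -0.648 with length and 0.495 with GC over 9852 genes. In the decile of genes with the shortest transcripts, 132 to 1158 bases, the median log2 change was 0.53, and in the decile with the longest it was -0.49. A smooth trend on both held 50.9% of the variance of the log2 changes. With the trend removed, 2996 genes rose and 2965 fell, 4321 calls had the same direction as without its removal, and 47 genes rose and 46 fell at least 2-fold. Pla2g7 (2.46), Timp1 (1.32), Ifnb1 (0.89), Gdf3 (-1.81), Ptgs2 (-0.92), Itgav (-0.95), Cpeb4 (-1.19), Bgn (1.35), Zeb2 (-1.07) and Gsdmd (-2.03) stayed past the threshold with the trend removed. So did Mt2 (0.52), Itga4 (-0.84), Lnpep (-0.85) and Dennd1b (-0.75). The changes of these 4 and of Ptgs2, Itgav and Cpeb4 were over 1.5 times larger as deposited. Values with the trend removed are given beside most gene groups below.

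**Figure D2:**
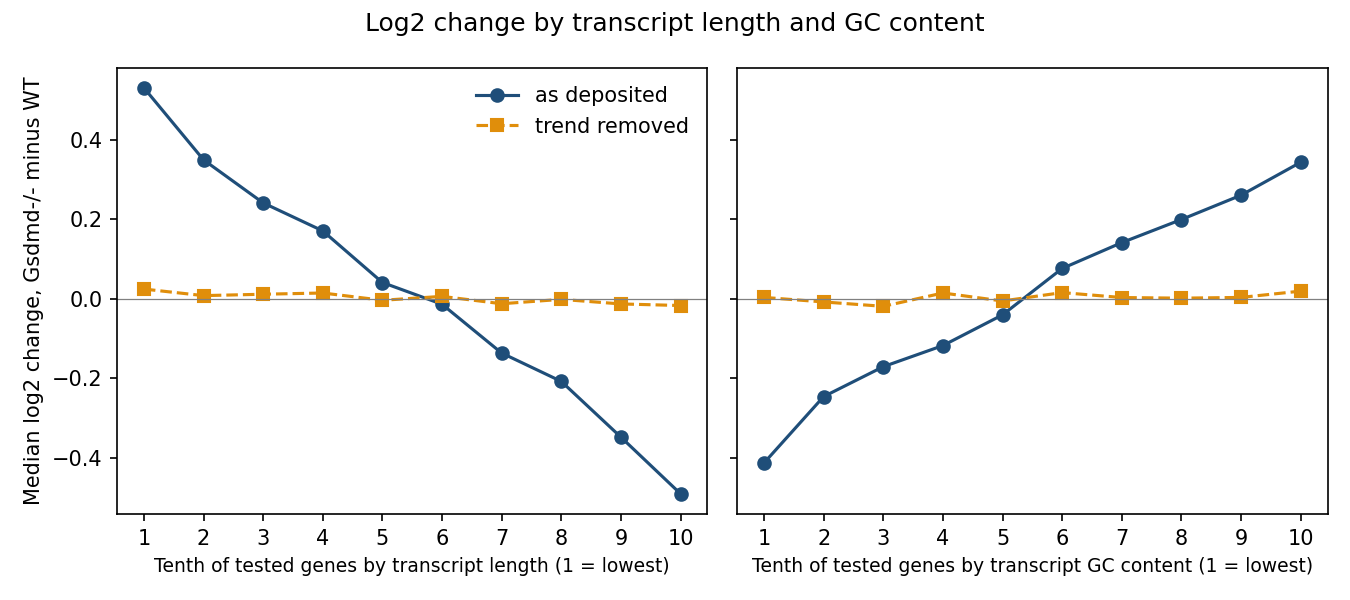
Median log2 change, Gsdmd-/- minus WT (vertical axis), in deciles of the tested genes ordered by transcript length (left) and GC content (right), as deposited (circles) and with the trend removed (squares). As deposited, the median went from 0.53 in the shortest to -0.49 in the longest decile, and from -0.41 in the decile lowest in GC to 0.34 in the highest.

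Genes of nuclear-encoded oxidative phosphorylation rose together: 49 of 53 tested members rose and 1 fell, over all genes tested and adjusted over the list alone, with a median log2 change of 0.55. Ndufb7, of respiratory complex I, rose from 64.1 ± 3.27 to 130 ± 3.71 FPKM, Atp5o from 112 ± 2.57 to 197 ± 4.66 FPKM and Cox4i1 from 233 ± 5.49 to 381 ± 4.71 FPKM (SD, n = 3 each). The list passed the test (camera, adjusted p = 2.35e-11), with an adjusted p = 0.226 with an estimated correlation. These transcripts are short. With the length and GC trend removed, the median was 0.08, 24 members rose and 8 fell (camera, adjusted p = 0.0205, and adjusted p = 0.151 with an estimated correlation), and Cox4i1 no longer passed (log2 change 0.05, adjusted p = 0.1).

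Proliferation genes rose, 27 of 35 tested members against 2 that fell, over all genes tested and adjusted over the list alone, with a median log2 change of 0.30. Birc5, a regulator of chromosome segregation, rose from 24.5 ± 1.21 to 44.2 ± 1.77 FPKM, Ube2c, which marks mitotic proteins for degradation, from 47.6 ± 2.58 to 79.1 ± 3.91 FPKM and Tk1, of thymidine salvage, from 8.11 ± 0.319 to 15.2 ± 0.901 FPKM. Stmn1, a microtubule regulator, rose by 0.65 on the log2 scale. The list passed (camera, adjusted p = 0.00045), with an adjusted p = 0.226 with an estimated correlation. With the length and GC trend removed its median was 0.40, with 28 members higher and 1 lower (camera, adjusted p = 1.08e-07, and adjusted p = 0.066 with an estimated correlation).

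Pattern recognition receptors and their adaptors, which detect microbial molecules, fell: 21 of 29 tested members fell and 4 rose, over all genes tested and adjusted over the list alone, with a median log2 change of -0.30. Tlr9, the receptor for unmethylated DNA, fell from 18.7 ± 0.346 to 6.32 ± 0.205 FPKM, Tlr3, which binds double-stranded RNA, from 99.3 ± 2.15 to 46.4 ± 2.03 FPKM and Tlr8 from 74.0 ± 2.80 to 37.9 ± 1.5 FPKM. Clec7a, which encodes the beta-glucan receptor dectin-1, fell from 346 ± 5.08 to 213 ± 1.93 FPKM. The list passed (camera, adjusted p = 0.00105), with an adjusted p = 0.226 with an estimated correlation. With the length and GC trend removed, 21 members fell and 2 rose, with a median of -0.25 (camera, adjusted p = 1.11e-05, and adjusted p = 0.131 with an estimated correlation).

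Chemokine genes were mostly higher, with 13 of 21 tested members up and 4 down over all genes tested and adjusted over the list alone. Ccl5 rose from 445 ± 17.0 to 867 ± 37.3 FPKM, Ccl4 from 2619.9 ± 29.9 to 4095 ± 13.2 FPKM, Ccl12 from 497 ± 3.36 to 764 ± 35.3 FPKM and Ccl8 from 67.1 ± 0.737 to 105 ± 2.46 FPKM, and all 4 stayed past the threshold with the length and GC trend removed. The list had a median log2 change of 0.30 (camera, adjusted p = 0.0372), with an adjusted p = 0.604 with an estimated correlation and 0.446 with the trend removed, where 11 members rose and 7 fell with a median of 0.16. After quantile normalization the median was 0.0033. The list did not pass under the stricter filter (0.197), quantile normalization (0.717), TPM (0.0527) or median ratio scaling (0.0524).

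Genes of MHC class I presentation were higher as deposited, 14 of 22 tested members up and 3 down over all genes tested and adjusted over the list alone, led by the immunoproteasome genes Psme2 (373 ± 1.90 to 546 ± 10.3 FPKM), Psmb10 (219 ± 9.83 to 358 ± 4.17 FPKM), Psmb8 and Psme1. The list passed (camera, adjusted p = 0.0373), with an adjusted p = 0.226 with an estimated correlation. It did not pass under the stricter filter (0.128), quantile normalization (0.543), TPM (0.402) or median ratio scaling (0.0673), or with the trend removed (0.251). Its direction depended on the scale: the median log2 change was 0.21 as deposited, -0.08 with the length and GC trend removed, where 5 members rose and 12 fell, -0.08 after quantile normalization and -0.01 in TPM. Psmb8 and Psme1 did not pass with the trend removed (adjusted p = 0.0675 and 0.0559).

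Markers of fibroblasts, a cell type outside the sorting gate, rose in Gsdmd-/- samples: 10 of 11 tested members rose and 0 fell over all genes tested, and 11 rose adjusted over the list alone, with a median log2 change of 0.999. Col1a1, a collagen gene, rose from 4.36 ± 0.334 to 13.4 ± 0.452 FPKM, Sparc, a matrix protein gene, from 5.16 ± 0.394 to 14.2 ± 0.176 FPKM and Bgn from 11.2 ± 0.601 to 33.0 ± 0.404 FPKM. Col6a1 rose by 1.07 on the log2 scale. The list passed (camera, adjusted p = 0.00045), with an adjusted p = 0.226 with an estimated correlation. With the length and GC trend removed its median was 1.08, with 11 members higher (camera, adjusted p = 1.87e-06, and adjusted p = 0.066 with an estimated correlation). Of the list of smooth muscle and enteric glia, 3 of 3 tested members rose: Acta2 from 2.2 ± 0.677 to 7.67 ± 0.516 FPKM, Tagln from 0.860 ± 0.676 to 3.93 ± 0.406 FPKM, and Uchl1 from 57.02 ± 1.41 to 91.0 ± 7.98 FPKM. In both lists a gene could enter on its level in the Gsdmd-/- samples alone, which favours rises among genes near the floor.

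**Figure D3:**
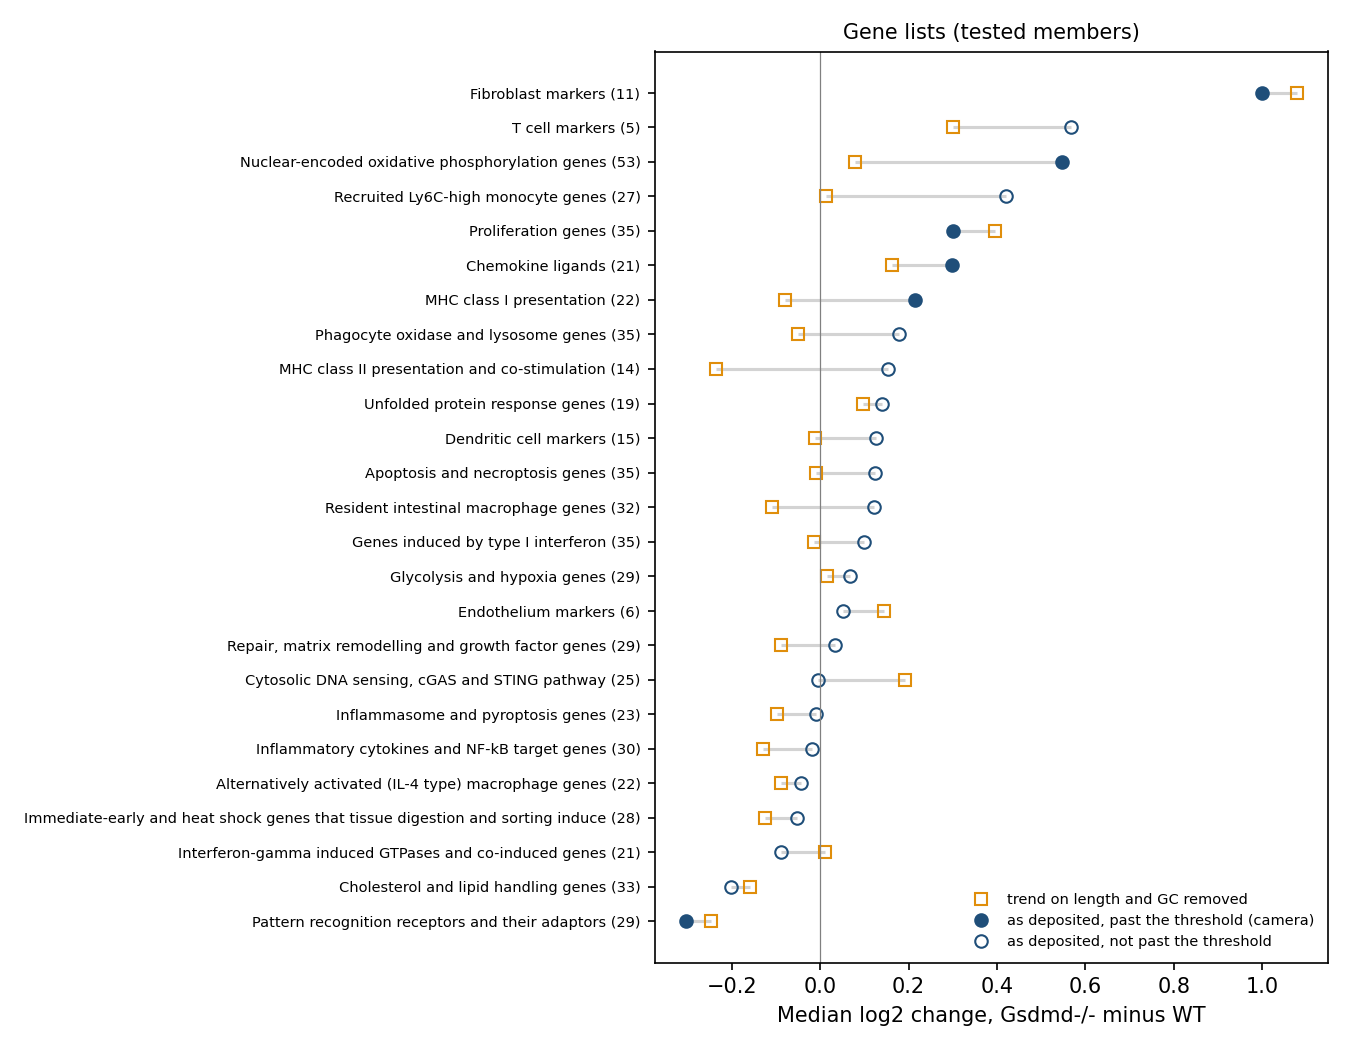
Median log2 change, Gsdmd-/- minus WT (horizontal axis), of the tested members of 25 gene lists, with their number in parentheses, as deposited (circles, filled where camera passed the threshold) and with the length and GC trend removed (squares). Fibroblast markers stood at 0.999 and 1.08, proliferation genes at 0.30 and 0.40, and pattern recognition receptors at -0.30 and -0.25, while oxidative phosphorylation genes went from 0.55 to 0.08.

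Among genes of cytosolic DNA sensing, Ifnb1 rose as given above, and Trex1, a nuclease that degrades cytosolic DNA, rose from 332 ± 6.68 to 545 ± 24 FPKM. Banf1, a DNA-binding protein gene, rose by 0.77 and Ifi207 fell by 0.39 on the log2 scale. Tmem173, which encodes STING, had a log2 change of 0.24 (adjusted p = 3.00e-05) and did not pass in TPM (adjusted p = 0.547). Cgas, the sensor upstream of STING, had a log2 change of -0.25 (adjusted p = 0.000418), and 0.06 with the length and GC trend removed. Of 25 tested members 10 rose and 9 fell, over all genes tested and adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.799, 0.828 with an estimated correlation). With the trend removed it passed upward (median 0.19, adjusted p = 0.0416, 0.173 with an estimated correlation).

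Genes induced by type I interferon moved both ways: of 35 tested members 20 rose and 13 fell, over all genes tested and adjusted over the list alone (camera, adjusted p = 0.530), and with the length and GC trend removed 14 rose and 11 fell. Ifit3 rose from 1149 ± 31.0 to 1801 ± 14.9 FPKM and Oas1a from 261 ± 3.36 to 380 ± 6.32 FPKM, while Cmpk2 fell from 2198 ± 19.7 to 1305 ± 43.5 FPKM and Ifit2 from 1383 ± 47.1 to 791 ± 23 FPKM. These 4 kept their direction with that trend removed. Isg15 had a log2 change of 0.42 as deposited and -0.11 with the trend removed. Cxcl10, at 7185 ± 64.7 FPKM in WT and 7232 ± 142 FPKM in Gsdmd-/-, had a log2 change of 0.01 (adjusted p = 0.703), and -0.23 with the trend removed. Of genes induced by interferon gamma, 5 of 21 rose and 11 fell, over all genes tested and adjusted over the list alone (camera, adjusted p = 0.261), and with the trend removed 7 rose and 7 fell (median 0.01, adjusted p = 0.905). As deposited, the GTPase genes Irgm2 and Gbp7 were lower by -0.88 and -0.94 and the chemokine gene Cxcl9 was higher by 0.57. Gbp2 had a log2 change of 0.42 as deposited and -0.01 after quantile normalization, where this list passed downward (median -0.33, adjusted p = 0.000903, with no estimated correlation run on that scale).

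In the inflammasome and pyroptosis list, 9 of 23 tested members rose and 11 fell, Gsdmd among them, over all genes tested and adjusted over the list alone (camera, adjusted p = 0.557). Il1b, which encodes interleukin-1 beta, fell from 269 ± 6.23 to 184 ± 2.46 FPKM (log2 change -0.55, adjusted p = 7.29e-09), and Nlrp3, an inflammasome sensor, from 54.1 ± 1.57 to 40.1 ± 1.19 FPKM. Nek7, a partner of Nlrp3, fell by 0.73 on the log2 scale. Casp4, the gene of the caspase that cleaves gasdermin D in response to lipopolysaccharide, rose from 122 ± 2.35 to 182 ± 5.02 FPKM. Casp1 had a log2 change of 0.20 as deposited and -0.02 in TPM, and Il18 one of 0.25 as deposited and 0.03 with the length and GC trend removed, where it did not pass. Aim2, a DNA sensor, was at 79.2 ± 1.44 and 79.3 ± 1.11 FPKM (adjusted p = 0.947), and its log2 change was 0.22 with the trend removed and -0.22 in TPM.

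Inflammatory cytokines and NF-kB targets included Rel, a subunit of NF-kB, which fell from 26.1 ± 1.33 to 9.29 ± 0.445 FPKM, Ptgs2 and Il1b, which also fell, and Saa3 and Il27, which rose by 0.96 and 0.71 on the log2 scale. Of 30 tested members 14 rose and 13 fell, over all genes tested and adjusted over the list alone (camera, adjusted p = 0.724). With the length and GC trend removed, 8 rose and 18 fell (median -0.13, adjusted p = 0.0416, 0.173 with an estimated correlation). MHC class II and co-stimulation genes rose in 9 and fell in 3 of 14 members (camera, adjusted p = 0.336), with Ifi30 and Cd40 higher by 0.86 and 0.39 and Ciita, the class II transactivator, and Cd80 lower by -0.80 and -0.51. With the trend removed, 2 of 13 members rose and 8 fell (median -0.24, adjusted p = 0.0205, 0.173 with an estimated correlation).

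Macrophage state lists moved both ways. Of resident intestinal macrophage genes 16 of 32 rose and 12 fell (camera, adjusted p = 0.724), and with the length and GC trend removed 9 rose and 17 fell, the median going from 0.12 to -0.11 (adjusted p = 0.251). Axl, a receptor for apoptotic cells, fell from 122 ± 0.583 to 61.7 ± 2.51 FPKM and the transcription factor gene Maf by 0.81 on the log2 scale, while Apoe and Folr2 rose by 0.82 and 0.61. Cx3cr1, a member outside the rule for named genes, was near the filter level, at 1.30 FPKM in WT and 1.36 FPKM in Gsdmd-/-. Its log2 change was 0.03 (limma, adjusted p = 0.724), and 0.20 with the trend removed. Of recruited monocyte genes 17 of 27 rose and 7 fell (camera, adjusted p = 0.0612). This list passed without WT replicate 2 (0.0455), without WT replicate 3 (0.0493), with the replicate block (0.0445), with no filter (0.0405), in TPM (0.0394), on ranks (0.034) and by fry (6.22e-05). It did not pass under the stricter filter (0.174), quantile normalization (0.391) or median ratio scaling (0.0723), and had an adjusted p = 0.231 with an estimated correlation. With the trend removed 13 rose and 10 fell, with a median of 0.01 against 0.42 (adjusted p = 0.677). Lyz1 was higher by 0.58 and Gpr141 lower by -0.87, and S100a4 was higher by 0.52. Of 2 members outside the rule for named genes, Ly6c2 was at 0.25 FPKM in both groups and was not tested. The other, Ccr2, fell from 2.78 to 1.30 FPKM (log2 change -0.71, limma, adjusted p = 2.36e-06, and -0.34 with the trend removed). S100a10 had a log2 change of 0.51 as deposited and 0.00 to 2 decimals with the length and GC trend removed, and S100a4 no longer passed (0.01). Alternative activation genes included Mrc1, Ccl22, Flt1 and Irf4, which fell by 0.59, 0.39, 1.02 and 0.90 on the log2 scale, with 7 of 22 members up and 9 down (camera, adjusted p = 0.502), and 5 and 11 with the trend removed. Of repair genes 12 of 29 rose and 10 fell (camera, adjusted p = 0.799), and 10 and 15 with the trend removed, with Hgf and Tgfbi lower by -1.06 and -0.37. The counts on deposited values are the same adjusted over the list alone.

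Among lysosomal and oxidase genes, 20 of 35 rose and 10 fell (camera, adjusted p = 0.261), and with the length and GC trend removed 13 rose and 15 fell, the median going from 0.18 to -0.05 (adjusted p = 0.877). Ctsb, a lysosomal protease gene, rose from 6200 ± 134 to 8999 ± 158 FPKM, Ctsc and Lamp2 fell by 0.54 and 0.48 on the log2 scale, and Ctsd had a log2 change of 0.38 as deposited and 0 after quantile normalization. Of apoptosis and necroptosis genes 19 of 35 rose and 12 fell (camera, adjusted p = 0.724), and 12 and 14 with the trend removed (adjusted p = 0.861). Xiap, Tnfsf10, Apaf1 and Mcl1 fell by 1.16, 0.87, 0.98 and 0.42. Hif1a, the hypoxia-response regulator, fell from 28.4 ± 0.772 to 12.1 ± 0.423 FPKM while the glycolytic genes Aldoa, Gpi1 and Eno1 rose by 0.58, 0.55 and 0.53, in a list with 15 of 29 members up and 8 down (camera, adjusted p = 0.336), and 11 and 10 with the trend removed. Of lipid handling genes 10 of 33 rose and 18 fell (camera, adjusted p = 0.336; 11 and 18 adjusted over the list alone): Plin2, of lipid droplets, rose by 0.60, and Abca1, the cholesterol exporter, and Cd36 fell by 1.37 and 0.62. The other 3 lists had the same counts adjusted over the list alone.

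Markers of other cell types were mostly near the floor: the mean was under 1 FPKM for 16 of 19 epithelial, 18 of 22 neutrophil, 14 of 17 muscle and glia and 8 of 18 fibroblast genes. Of the neutrophil list 4 members were tested and 4 rose, led by Mmp9 (1.56 ± 0.0666 to 3.43 ± 0.0577 FPKM) and Csf3r (0.33), with Mmp8 and Cxcr2 not past the threshold in TPM (adjusted p = 0.197 and 0.0998). Epithelial markers fell in 3 of 3 tested, with Car2 from 18.7 ± 1.17 to 9.48 ± 0.257 FPKM, Cdh1 lower by -0.52 and Ceacam1 by -0.23, which did not pass after quantile normalization (adjusted p = 0.0603). T cell markers rose in 3 and fell in 2 of 5 (camera, adjusted p = 0.641): Lck and Cd8b1 rose by 0.63 and 0.57, Lat rose by 0.59 but did not pass with the length and GC trend removed (0.07), and Cd28 had a log2 change of -0.35 as deposited and 0.12 with that trend removed. Dendritic cell markers rose in 7 and fell in 6 of 15 (camera, adjusted p = 0.911), with Fscn1 and Batf3 higher by 1.03 and 0.90, and Bst2 by 0.58 as deposited and -0.02 with the trend removed. Endothelial markers rose in 2 and fell in 2 of 6 (camera, adjusted p = 0.799), with Kdr lower by -1.08, Plvap higher by 0.80 and Eng by 0.15 as deposited and -0.07 in TPM.

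Of the remaining marker lists, eosinophil genes rose in 1 (Ccl6, log2 change 0.30 as deposited and -0.14 after quantile normalization) and fell in 2 of 4 (Ccr3, -0.72, and Siglecf, -0.36); Clec12a had a log2 change of 0.00 to 2 decimals, -0.22 in TPM and 0.21 with the length and GC trend removed. The NK and innate lymphoid list had Il7r lower by -0.82 and Klrk1 at 0.13 (adjusted p = 0.253; 0.0301 without Gsdmd-/- replicate 1). The B and plasma cell list had Cd22 higher by 0.38, with Xbp1 at 0.05 (adjusted p = 0.180) as deposited and -0.15 with the trend removed, and Sdc1 at 19.4 FPKM in both groups (adjusted p = 0.988), with a log2 change of -0.22 in TPM (adjusted p = 0.00162). The mast cell and basophil list had Kit lower by -0.62 and Hdc at 0.19 as deposited and -0.01 in TPM, lost without Gsdmd-/- replicate 1 (adjusted p = 0.0517). The red cell list had Bpgm higher by 0.25, which did not pass in TPM (adjusted p = 0.352). Genes that digestion and sorting induce rose in 12 and fell in 12 of 28 (camera, adjusted p = 0.971), and in 7 and 13 with the trend removed (adjusted p = 0.202), with Fos and Klf6 lower by -0.50 and -0.55, Hsp90aa1 higher by 0.65 and Hspa8 at 0.36 as deposited and -0.08 after quantile normalization. Unfolded protein response genes rose in 12 and fell in 3 of 19 (camera, adjusted p = 0.129, 0.0449 with no filter, 0.232 with the trend removed, and adjusted p = 0.604 with an estimated correlation), with Asns and Pdia6 higher by 0.63 and 0.43, Canx lower by -0.51 and Calr at 0.33 as deposited and -0.14 after quantile normalization. The counts on deposited values are the same adjusted over the list alone. The median of the list and the direction of camera differed in sign for DNA sensing (median -0.01, test upward), the sorting stress list (-0.05, upward) and endothelial markers (0.05, downward).

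The genes next to Gsdmd were tested because a targeted allele can carry flanking DNA of another strain. Of 40 annotated neighbours, between positions 75348617 and 76120195 of chromosome 15, 10 were tested, and 9 rose and 0 fell over all genes tested and adjusted over the list alone. With the length and GC trend removed 4 rose and 0 fell, with Zc3h3 at 0.53 and Eef1d at 0.37, both named after their values were seen. The median of the neighbours was then 0.07. Over all genes, 4059 of 10005 rose as deposited and 2996 of 9852 with the trend removed. Only 10 of the 40 neighbours were tested, and their sequence was not examined, so the counts cannot decide on flanking DNA of another strain.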

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

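The removal of the length and GC trend was chosen after seeing the data, and the other alternatives before. Gsdmd stayed lower and past the threshold under every one of them, at -1.71 to -1.74 with a sample left out and -2.03 with the trend removed. With a sample left out, 7375 to 7604 genes passed (3867 to 3982 higher, 3507 to 3659 lower), 263 to 329 at least 2-fold (70 to 80 higher, 192 to 251 lower), and 6 to 7 lists, and of the 7752 calls 7301 to 7439 kept their side of the threshold with 0 changes of sign. The stricter filter, with fewer genes tested, left 49 genes higher at least 2-fold. In TPM, 2575 genes were higher, and 738 changed and 675 fell at least 2-fold, with the median of all genes at -0.17. A pseudocount of 0.1 gave 588 genes changed at least 2-fold (175 higher, 413 lower) and one of 0.01 gave 644 (192 higher, 452 lower), since a smaller pseudocount widens changes at low level. With the trend removed, 93 changed at least 2-fold (47 higher, 46 lower). Of the 6 lists called, 0 passed with an estimated correlation, while fry, which does not compare a list with other genes, called 21. The estimated correlation was -0.089 for fibroblast markers and -0.01 for MHC class I, below the preset 0.01. It was 0.019 for proliferation, 0.034 for pattern receptors, 0.133 for oxidative phosphorylation and 0.151 for chemokines. Correlated members therefore do not account for the lost calls of fibroblast markers and MHC class I. With an estimated correlation, camera also took its degrees of freedom from the 6 samples, and at the preset from the number of genes. This weakens every list, so the lost calls of the other lists cannot be credited to correlated members alone. Quantile normalization took Ctsd to 0 and reversed Gbp2 (-0.0054), Ccl6 (-0.14), Clec12a (-0.27), Hspa8 (-0.0826), Calr (-0.14), Casp1 (-0.0423), Aim2 (-0.09), Isg15 (-0.0056), Cxcl10 (-0.26) and the MHC class I list (-0.0847). TPM reversed Clec12a (-0.22), Xbp1 (-0.17), Hdc (-0.0059), Eng (-0.0724), Casp1 (-0.0181), Aim2 (-0.22) and Cxcl10 (-0.21). Removing the trend reversed S100a10 (-0.0022), Bst2 (-0.0167), Cd28 (0.12), Xbp1 (-0.15), Cgas (0.0619), Isg15 (-0.11), Cxcl10 (-0.23) and the lists of MHC class II (-0.24) and MHC class I (-0.0784). The cause of these reversals was not tested. A reversal was counted only where the gene or list passed the threshold as deposited or under the alternative, with the direction of a list taken from camera. Changes of sign between values that did not pass, such as could arise for genes near 0, are not listed. Across the alternatives fixed beforehand, 2262 values of named genes kept their side of the threshold, and also their direction where they passed it. Of the others, 7 lost their call, 2 gained one and 17 reversed or, for Ctsd, went to 0. With the replicate number as a block, 7801 genes (4095 higher, 3706 lower) and 7 lists passed, 7679 of the calls shared; same-numbered samples deviated from their group means with correlations of -0.08, 0.13 and 0.01, so the numbers do not pair the samples. The estimated depth limits genes at low level, and in 10 of the 12 lists of other cell types the median member was under 1 FPKM.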

Other observations

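All tests of explanations in this part, and the genes named here that the rule does not name, were chosen after their values or the pattern had been seen.

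The genes of the 3 proteins used for sorting were lower in Gsdmd-/- macrophages. Itgam, which encodes the CD11b chain, fell from 177 ± 3.24 to 91.3 ± 4.07 FPKM (SD, n = 3 each, log2 change -0.94, adjusted p = 1.21e-09), Ptprc, which encodes CD45, from 92.4 ± 4.73 to 57.9 ± 2.50 FPKM and Adgre1, which encodes F4/80, from 291 ± 4.29 to 216 ± 5.67 FPKM. Each was also lower after quantile normalization, in TPM and after median ratio scaling, and with the length and GC trend removed, at -0.65 for Itgam, -0.28 for Adgre1 and -0.17 for Ptprc. The protein levels behind the gate were not analysed here.

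Log2 changes followed transcript length and GC across 9852 genes. Without 352 ribosomal, respiratory chain, proteasome, RNA polymerase and small nuclear ribonucleoprotein genes, the Spearman rho with length was -0.632, beside -0.648 with them. The trend was therefore not confined to these pathways with short mRNAs. The share of genes left out could move a rank correlation only a little, so this test could not weigh their contribution. A difference between libraries in the recovery of transcripts may contribute: samples of the same group differed along length too, with an absolute rho of up to 0.375 among the 6 pairs, though less than between the groups. The labels give no library batch, so such a difference and a real shift between short and long mRNAs in Gsdmd-/- macrophages stay open, the latter untested.

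Fibroblast and smooth muscle genes were higher in Gsdmd-/- samples. The length and GC trend was argued against as the source, since with it removed the fibroblast list had a median log2 change of 1.08. For a general loss of macrophage share, 44 pooled markers of other cell types were examined with the trend removed. Their median was 0.0948 (bootstrap standard error 0.0694), with 19 higher and 14 lower. Only markers that passed the filter on level in the sorted cells were pooled. Whether macrophages express these markers themselves was not tested, so the pool cannot decide on a loss of macrophage share. For stromal cells or their RNA among the sorted cells, a further list of stromal genes was drawn up: of 32 tested, 24 (75%) were higher and 5 lower with the trend removed, short of the share set for this explanation and above the one set against it, so that it cannot be told apart from a change within macrophages. Among them, Pcolce rose from 1.72 to 6.28 FPKM and Serpinf1 from 2.24 to 7.07 FPKM, while Cav1 fell from 7.35 to 4.41 FPKM. Here too a gene near the floor could pass the filter on its level in the Gsdmd-/- samples alone, which favours rises. The sort for CD45 would remove stromal cells, no tested gene of the fibroblast or smooth muscle lists is in a list of other cells or functions, and expression of these genes by Gsdmd-/- macrophages was not tested.

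The Dynlt1, Entpd4 and 9930111J21Rik gene families, each of near-identical copies, changed strongly. In the Entpd4 family, Gm16867 went from 4.63 to 0.09 FPKM, Entpd4b from 11.9 to 4.44 FPKM and Entpd4 from 2.99 to 4.50 FPKM. Reads moved between copies were argued against as the whole source: summed over copies, Dynlt1 went from 84.8 ± 3.43 to 205 ± 8.93 FPKM, Entpd4 from 19.52 ± 0.934 to 9.03 ± 0.335 FPKM and 9930111J21Rik from 97.7 ± 8.45 to 22.7 ± 2.44 FPKM, and the smallest absolute log2 change of a sum was 1.03. A difference in C57BL/6 substrain between the groups cannot be told apart from an effect of Gsdmd: 6 tested genes of 8 listed as differing between substrains had a median absolute log2 change of 0.466 with the length and GC trend removed, at the 99.15 percentile of 10000 sets matched on level, but without Entpd4, itself of these families, the 5 others were at the 94.77 percentile, short of the bound set. Nnt, one of them, went from 5.07 to 8.57 FPKM, while Entpd4 (adjusted p = 0.118) and Cyfip2 (adjusted p = 0.117) did not pass with the trend removed. The labels name no substrain, and an effect of Gsdmd on the families was not tested.

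The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 7752 genes, 295 genes changed at least 2-fold and 6 lists, and the highest of the others gave 0 genes, 0 genes and 4 lists. Every other split put both genotypes in each group, which widens the spread within groups, so its 0 genes are no support for the real split.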
